A study of Homo sapiens with 12 samples.

How the data were processed

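RNA was measured in 12 libraries of SET-2 cells, in 4 groups of 3, with wild-type LSD1 (WT) or LSD1 with an inserted arginine (insR), given DMSO or GSK-LSD1 for 48 h. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

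Libraries were made from polyadenylated RNA with a QuantSeq 3' forward kit, per the labels' protocols, so reads lie near transcript ends. The tools bcl2fastq 2.2, STAR 2.6.0c, HTSeq 0.9.1 and DESeq2 and the build hg19 are named in the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are uncertain. The deposited counts are whole reads per gene with no normalization. The deposited table of normalized signal holds those counts divided by 1 size factor per library. Multiplying by the factor gave whole reads for 100% of nonzero values in each library, to a tolerance of 0.01, and 0 genes differed from the deposited count.

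The count tables list 63677 genes, of which 52526 matched a symbol by Ensembl identifier and 27370 had a read. Reads in genes numbered 4837096 to 10141155 per library. Entries that name no gene were kept out of library sizes and tests. The entry for alignments that were not unique made up 57.9% to 62.6% of each table's total, and ambiguous reads 0.68% to 0.75%. The first entry may count a read once per alignment, so it is not taken as a share of reads. Reads outside any gene made up 13.7% to 19.5% of uniquely aligned reads. The limit that a count of 0 allows, 3 counts, was worth 0.296 to 0.62 CPM per library. Intervals and floors cover counting error only. HBA1 and HBA2, HBG1 and HBG2, and the HLA genes have near-identical copies and their separate values are uncertain.

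The groups, comparisons, tests, alternatives, 20 gene lists and the rule for naming genes were chosen before the data were examined. The test was the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and filterByExpr, fitted to all 12 libraries. Adjusted p-values are Benjamini-Hochberg values over the 12864 genes tested, and genes were called below 0.05. The comparisons were GSK-LSD1 against DMSO in WT and in insR cells, the difference between these responses, and insR against WT cells in DMSO. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison.

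KDM1A was named first. Other named genes were called, protein-coding, at a mean of at least 10 CPM in the higher group and without overlap between the libraries compared, which was not asked of the difference in response. The 10 largest changes per direction were taken for the WT response and for insR against WT in DMSO, and 5 for the others, with up to 4 members of lowest p per list. Some items that the rule names are not reported here. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts in a group, the ratio is of summed counts over summed scaled library sizes, so it can differ from a ratio of mean CPM.

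The WT response and the DMSO comparison share the WT DMSO libraries, so their relation was set beside 50 simulations of unchanged groups. Alternatives were DESeq2 size factors, upper-quartile scaling, other count filters, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited normalized signal plus 1, a replicate block, stricter thresholds, fits on only the groups compared, and each library left out in turn, and these were fixed with the tests. Libraries thinned to equal depth and a minimum of 10 CPM for the relation were added after seeing the data.

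The fits were tested on simulated counts of 12864 genes with 200 changed. At 2-fold edgeR recovered 68.7% for the WT response, 80.6% for the insR response, 58.2% for the difference in response and 77.6% for insR against WT in DMSO. False calls over all fold sizes numbered 6, 7, 5 and 7. Gene order was taken from a GENCODE annotation of a later build than the authors' hg19, so only names, chromosomes and neighbours were used. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.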

Results

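Transcript levels were measured in SET-2 cells, an established human acute myeloid leukemia line, with wild-type (WT) LSD1 or with LSD1 carrying an inserted arginine (insR). LSD1 is a histone demethylase encoded by KDM1A, and the labels call the insR cells drug-resistant. Cells received 250 nM GSK-LSD1, an irreversible LSD1 inhibitor, or 0.1% (v/v) DMSO for 48 h, with 3 libraries in each of 4 groups. Reads in genes ranged from 5562853 to 7438754 in WT DMSO, 5022916 to 9599482 in WT GSK-LSD1, 5789614 to 10141155 in insR DMSO and 4837096 to 6615832 in insR GSK-LSD1. In multidimensional scaling the first dimension, with 65.2% of the variance, separated insR from WT libraries. It also set treated WT libraries, at -2.19 to -2.15, apart from WT DMSO, at -0.91 to -0.83. The second dimension, with 17.3%, separated treated from untreated WT libraries as well.

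KDM1A, the gene of the drug's target, was at 265 ± 26.5 CPM (SD, n = 3) in WT DMSO and 217 ± 3.01 in WT GSK-LSD1. It was at 109 ± 2.18 CPM in insR DMSO and 106 ± 4.56 in insR GSK-LSD1. The log2 fold change of insR against WT in DMSO was -1.28 (SE 0.08, edgeR adjusted p = 7.64e-12). In WT cells KDM1A fell under the drug, with a log2 fold change of -0.29 (adjusted p = 0.00451). Gene counts do not show the insertion, so this level does not check the labels.

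**Figure D1:**
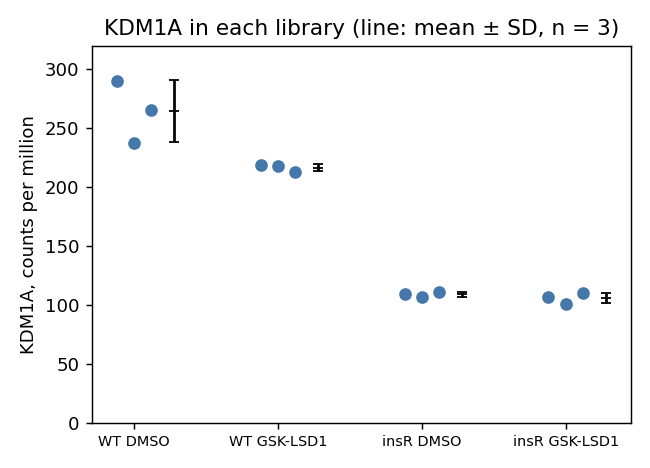
KDM1A in CPM (reads scaled to a common library size) in each of the 12 libraries, by group, with the mean and SD of each group (n = 3) beside the points. The insR libraries lay between 101 and 111 CPM and the WT libraries between 213 and 290 CPM.

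The first comparison asked which transcripts changed under GSK-LSD1 in WT cells. EPAS1, a hypoxia-inducible transcription factor, rose from 1.42 ± 0.481 to 109 ± 8.89 CPM (SD, n = 3), and TIMP2, a metalloproteinase inhibitor, from 2.2 ± 0.708 to 201 ± 19.4. CD36, a fatty acid receptor, fell from 172 ± 6.73 to 6.51 ± 1.57 CPM. Erythroid, cholesterol synthesis and ribosome biogenesis genes fell as groups, and MHC class II genes, stem cell genes and the tested monocyte genes rose as groups. Of 12864 genes tested, 5816 were called by edgeR, 2916 higher and 2900 lower. Of these 1557 changed at least 2-fold, 997 upward and 560 downward.

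Among the largest increases, PI16 had 0 counts in WT DMSO and 33.4 ± 2.77 CPM after GSK-LSD1, at least 205-fold higher (adjusted p = 2.59e-12). The lectin receptor CLEC4A reached 78.5 CPM from 0.208, the junction protein JAML 45.5 from 0.445, and PRR9 64.6 from 0.872. MPZL2 rose from 0.194 to 12.3 CPM. With 1 to 3 counts in WT DMSO, the ratios were 269 for the kinase MAPK13 (95% counting interval 47.8 to 10600), 102 for SNX21 (34.7 to 498) and 69.5 for CRYBG1 (23.5 to 340). Among the largest decreases, the water channel AQP1 fell from 25.2 ± 3.1 to 0.162 ± 0.199 CPM, with a ratio of summed counts, scaled to library size, of 169 (57.3 to 821). OSBP2, DHH and the gap junction gene GJA4 fell with log2 fold changes of -3.98, -3.97 and -3.93. AQP3 fell from 56.8 ± 40.6 to 1.46 ± 1.28 CPM (adjusted p = 0.00519), and limma-voom did not call it (adjusted p = 0.133, with 9.85e-09 to 0.133 over all alternatives).

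Of 22 erythroid genes tested, 21 fell (camera adjusted p = 7.59e-37). HBG1, HBG2, HBA1 and HBA2, globin genes whose near-identical copies can share reads, had log2 fold changes of -3.05, -3.54, -3.50 and -3.61, and the membrane skeleton gene ANK1 had -2.11 (SE 0.10). Of 16 cholesterol synthesis genes 13 fell (adjusted p = 1.07e-09), or 14 adjusted over the list alone, HMGCS1 at -1.42 and DHCR7 at -1.33. Ribosome biogenesis genes fell in 19 of 19 cases (adjusted p = 6.03e-08), NOP16 at -1.39 and NIP7 at -1.10. Of 32 cell cycle genes 22 fell (adjusted p = 0.000238), CDC20 at -0.77 and CCNA2 at -0.68. In the hypoxia and glycolysis list 9 of 15 genes fell and 2 rose (adjusted p = 0.000274), with the glucose transporter SLC2A1 at -2.05 and VEGFA at -1.55.

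MHC class II genes rose in 10 of 11 cases (adjusted p = 6.28e-07), HLA-DRA by 1.47 and the invariant chain CD74 by 1.35. Of 10 monocyte and macrophage markers 6 rose and 1 fell (adjusted p = 0.000257), or 7 and 1 adjusted over the list alone, with VCAN at 4.05 and the integrin ITGAM at 1.80. The count filter left 10 of 25 listed monocyte markers, and CD14 and CSF1R were among those too low to test. Stem and progenitor genes rose in 7 of 12 cases (adjusted p = 1.48e-05), CD34 by 1.24 and ERG by 1.43. The lists named so far also passed with an estimated correlation. Among 28 haematopoietic transcription factors 12 rose and 9 fell, or 12 and 10 adjusted over the list alone. GFI1, a repressor that recruits LSD1, rose by 3.48 (SE 0.12), GFI1B by 1.55 and RUNX1 by 1.31. That list had an adjusted p = 0.027, but an adjusted p = 0.0529 with an estimated correlation and 0.0752 without WT DMSO replicate 3 (range over alternatives 5.36e-07 to 0.0752).

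STAT5 targets fell in 9 cases and rose in 1 (adjusted p = 0.015, but adjusted p = 0.156 with an estimated correlation), PIM2 at -0.99 and CCND2 at -0.54. Heat shock and integrated stress genes fell in 8 cases and rose in 3 (adjusted p = 0.0476, but adjusted p = 0.0879 with an estimated correlation), with the chaperonin HSPE1 at -1.14 and ATF3 at 3.39. Mast cell, basophil and eosinophil genes rose in 4 cases and fell in 1 (adjusted p = 0.0395, but adjusted p = 0.128 with an estimated correlation), IL5RA at 4.65 and KIT at -0.68. Without WT DMSO replicate 3 the adjusted p was 0.065 for the heat shock list (range over alternatives 8.61e-06 to 0.0879) and 0.0649 for the mast cell list (0.000124 to 0.128).

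The remaining lists did not pass with camera in WT cells. Neutrophil genes had 4 higher of 7 (adjusted p = 0.1), and megakaryocyte genes 4 higher and 7 lower of 15 (adjusted p = 0.1), with RAB27B at 2.01 and GP6 at -3.03. Interferon response genes had 9 higher and 4 lower of 23 (adjusted p = 0.64), with RSAD2 at 1.80. Inflammatory and NF-kB genes had 3 higher of 9 (adjusted p = 0.1), and p53 targets 6 higher and 4 lower of 20 (adjusted p = 0.64). LSD1 complex genes had 3 higher and 3 lower of 17 (adjusted p = 0.913), and lymphoid markers 3 higher of 6 (adjusted p = 0.203). Mitochondrial mRNAs had 1 higher and 2 lower of 13 (adjusted p = 0.643), or 0 and 1 adjusted over the list alone. The count filter left 7 of 20 neutrophil, 15 of 25 megakaryocyte, 10 of 18 mast cell, 9 of 18 inflammatory and 6 of 14 lymphoid genes that were listed and found in the tables. Of the lymphoid calls, CD79A was lost without WT DMSO replicate 2 or 3 or WT GSK-LSD1 replicate 1 or 2 (adjusted p 0.0749 to 0.106). NKG7 was lost without any 1 of the WT libraries (adjusted p 0.0684 to 0.12), with no filter beyond 1 count (0.156), with DESeq2 (0.0866) and with limma-trend (0.0699). Of the mitochondrial calls, MT-ND4L was lost without replicate 2 or 3 of either WT group (adjusted p 0.0555 to 0.141) and with upper-quartile scaling (0.0782), and MT-CO2 without replicate 1 or 3 of either (adjusted p 0.0596 to 0.136). Over all alternatives the adjusted p ranged from 0.0153 to 0.106 for CD79A, 0.0308 to 0.156 for NKG7, 0.00342 to 0.141 for MT-ND4L and 0.00677 to 0.136 for MT-CO2. For WT lists given without a count adjusted over the list alone, that adjustment gave the same numbers. With fry, which tests whether members move on balance one way and does not compare them with other genes, the adjusted p was 0.000567 for neutrophil, 0.000188 for megakaryocyte, 0.0278 for interferon, 0.000463 for inflammatory, 0.00769 for p53 and 0.000102 for lymphoid genes. It was 0.465 for LSD1 complex genes and 0.629 for mitochondrial mRNAs. Treated WT libraries had 18.4% to 19.5% of uniquely aligned reads outside genes, against 16.3% to 16.7% in WT DMSO. Their mitochondrial shares averaged 4.16% against 3.25%. These shares count all genes whose symbol starts with MT-, not only the 13 tested mRNAs, whose mean log2 fold change was -0.13.

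**Figure D2:**
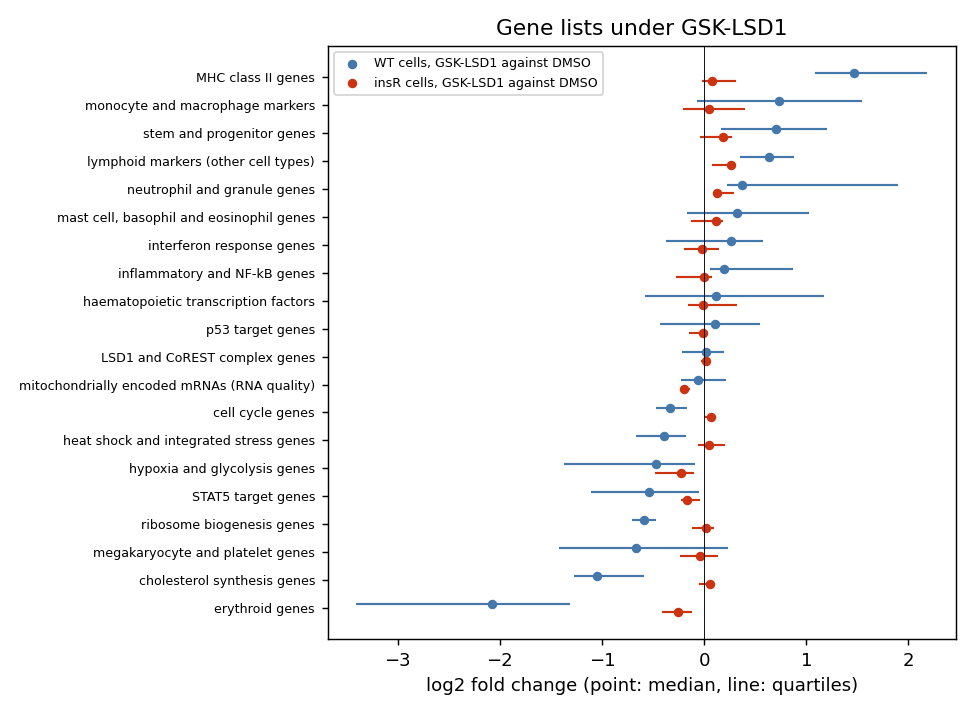
Median log2 fold change (x axis) of the tested members of each of the 20 gene lists under GSK-LSD1, in WT and in insR cells, with lines from the lower to the upper quartile. The erythroid median was -2.08 in WT and -0.26 in insR cells, and the MHC class II median was 1.47 and 0.072.

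The same treatment was then compared in insR cells. DHRS9, a retinol dehydrogenase, rose from 49.6 ± 2.08 to 129 ± 9.48 CPM (SD, n = 3), and GDF3, a growth factor of the TGF-beta family, from 26.9 ± 1.21 to 60.4 ± 2.51. EGR1, an immediate early transcription factor, fell from 66 ± 3.79 to 23.3 ± 4.69 CPM, and the scaffold gene AKAP12 from 480 ± 80.4 to 254 ± 42.4. PHGDH rose to 20.9 ± 1.85 CPM from 10.4 ± 2.6, STAB1 to 15.3 ± 2.05 from 7.45 ± 2.05 and FAM111B to 36 ± 2.49 from 19.7 ± 3.4. edgeR called 65 genes, 31 higher and 34 lower, with 11 changed at least 2-fold, and 996 genes had an unadjusted p under 0.05. The count was 29 without insR DMSO replicate 1, 34 without its replicate 2, 28 without insR GSK-LSD1 replicate 1, 28 without its replicate 2 and 40 without its replicate 3. It was 118 with no filter beyond 1 count and 39 by limma-trend.

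NSG1, SLC6A8 and LBH had log2 fold changes of -0.96, -0.93 and -0.92 in insR cells (adjusted p = 0.0257, 0.0177 and 0.0175). The NSG1 call was lost without insR DMSO replicate 1 or 3 or any insR GSK-LSD1 library (adjusted p 0.0631 to 0.192) and with limma-voom (adjusted p = 0.0589). The calls of SLC6A8 and LBH were lost without insR DMSO replicate 1 or 2 or any insR GSK-LSD1 library (adjusted p 0.0506 to 0.17 and 0.0506 to 0.21) and with limma-trend (adjusted p = 0.0621 and 0.0509). Over all alternatives the adjusted p ranged from 0.00201 to 0.192 for NSG1, 0.00106 to 0.17 for SLC6A8 and 0.00129 to 0.21 for LBH.

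Erythroid genes were lower as a group in insR cells (camera adjusted p = 1.49e-12, 0.000708 with an estimated correlation), with 3 of 22 called, or 9 adjusted over the list alone. These were HBA2, HBA1 and HBE1, with log2 fold changes of -0.78 (SE 0.13), -0.54 and -0.39. The HBA1 call was lost without insR DMSO replicate 1 or insR GSK-LSD1 replicate 1 or 2 (adjusted p 0.0907 to 0.107), and the HBE1 call without any 1 of the insR libraries (adjusted p 0.0856 to 0.177). Limma-trend called neither HBA1 (adjusted p = 0.0539, with 4.5e-05 to 0.107 over all alternatives) nor HBE1 (adjusted p = 0.0811, with 0.0147 to 0.177). Hypoxia and glycolysis genes were also lower (adjusted p = 2.43e-09, 0.00552 with an estimated correlation), with 1 of 15 called, or 6 adjusted over the list alone. Its called member NDRG1 was at -0.70 (adjusted p = 0.00595, and 0.0506 without insR GSK-LSD1 replicate 3, with 0.00163 to 0.0506 over all alternatives). Stem and progenitor genes (adjusted p = 0.0239), STAT5 targets (adjusted p = 0.0432) and mitochondrial mRNAs (adjusted p = 0.000725) passed only at the preset correlation. With an estimated correlation the adjusted p of these lists was 0.21, 0.329 and 0.371, and edgeR called 0 members of each, or 2, 1 and 0 adjusted over the list alone. With fry it was 0.054, 0.191 and 0.315. The stem cell list had adjusted p = 0.0814 or 0.0743 without insR DMSO or GSK-LSD1 replicate 2. The STAT5 list had 0.204 or 0.108 without insR DMSO replicate 2 or 3, and 0.071 or 0.0743 without insR GSK-LSD1 replicate 1 or 2. The mitochondrial list had 0.0589 without insR DMSO replicate 3 and 0.289 without insR GSK-LSD1 replicate 1. Over all alternatives the adjusted p ranged from 0.0236 to 0.21, 0.00602 to 0.329 and 9.46e-10 to 0.371 for these lists. GFI1B rose by 0.55 (SE 0.08, adjusted p = 0.00112). MHC class II genes did not pass with camera (adjusted p = 0.146) and passed with fry (adjusted p = 0.0194, with 0.0194 to 0.434 over all alternatives). Both tests pointed upward, with a median of 0.072 and a mean of -0.0075.

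Genes called in WT cells were followed in insR cells. Across the 5816 WT calls, the median log2 fold change signed by the WT direction was 0.051 in insR and 0.65 in WT cells, or 7.9% of it. The sign was shared by 63.9% of these genes. Of the 31 genes higher in insR cells 30 were also higher in WT, where independent lists would share 7. Of the 34 lower genes 21 were also lower in WT and 8 were higher, where independent lists would share 7.7 in either case.

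**Figure D3:**
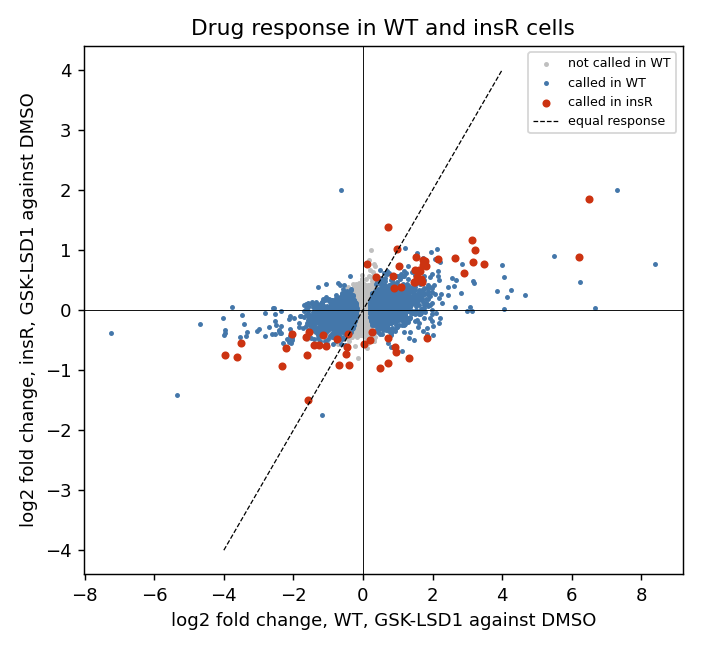
Log2 fold change under GSK-LSD1 in WT cells (x axis) and in insR cells (y axis), 1 point per gene with a mean of at least 10 CPM, with a dashed line of equal response. The WT calls had a median log2 fold change, signed by the WT direction, of 0.051 in insR cells.

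The difference between the responses of insR and WT cells was tested as an interaction. CD36 went from 236 ± 10.6 to 199 ± 8.03 CPM in insR cells (interaction adjusted p = 1.79e-16), AQP1 from 65.4 ± 3.12 to 50.1 ± 4.9 (adjusted p = 4.18e-12) and the red cell gene EPB42 from 58.6 ± 3.73 to 60.5 ± 6.67 (adjusted p = 9.89e-09). CR2 and DHH had adjusted p = 5.8e-06 and 3.52e-08. JAML was at 0.264 ± 0.245 CPM in treated insR cells (adjusted p = 0.000117) and BACH2 at 0.159 ± 0.161 (adjusted p = 6.99e-05). edgeR called 3228 genes, 1711 with a more positive and 1517 with a more negative response in insR cells.

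The interaction calls of PI16, CLEC4A and MAPK13, with few counts in insR cells, were each lost when 1 library was left out. PI16 had an interaction adjusted p = 0.00103, and 1 without insR DMSO replicate 3. CLEC4A had 0.014, and 0.0984 or 0.104 without insR DMSO replicate 1 or 2. MAPK13 had 0.018, and 0.968 without insR DMSO replicate 1. For PI16 and MAPK13 the library left out held the only reads of insR DMSO, so the rest of that group was at 0. No fold can be estimated from such a group, and the lost calls do not show an equal response. After GSK-LSD1, MAPK13 was at 14.8 CPM in WT and 0.138 in insR cells, and PI16 at 33.4 and 0. Over all alternatives the adjusted p ranged from 1.19e-07 to 1 for PI16, 4.92e-07 to 0.104 for CLEC4A and 3.8e-05 to 0.968 for MAPK13.

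The response was more positive in insR cells for 19 of 22 erythroid genes (camera adjusted p = 1.02e-39), 13 of 16 cholesterol synthesis genes (adjusted p = 5.25e-12), 17 of 19 ribosome biogenesis genes (adjusted p = 4.31e-09) and 17 of 32 cell cycle genes (adjusted p = 4.63e-06). It was more negative for 9 of 11 MHC class II genes (adjusted p = 9.9e-07), 4 of 10 monocyte markers (adjusted p = 0.000743) and 5 of 12 stem and progenitor genes (adjusted p = 0.00104). Heat shock and integrated stress genes had 8 more positive and 2 more negative members (adjusted p = 0.00941). These 8 lists also passed with an estimated correlation. Adjusted over the list alone the numbers were 20 more positive and 1 more negative for erythroid genes and 20 for cell cycle genes, with the others as given. HBG1 and HMGCS1 differed by log2 values of 2.69 and 1.51, and GFI1, HLA-DRA and VCAN by -2.71, -1.25 and -4.04. Hypoxia and glycolysis genes, lower as a group in both cells, did not pass (camera adjusted p = 0.0539). With an estimated correlation the adjusted p was 0.149, and with fry 0.00342. Their median log2 fold change was -0.47 in WT and -0.22 in insR cells. MHC class II genes already lay higher in insR DMSO, by a median of 1.60 against WT DMSO. Their median under the drug was 1.47 in WT cells.

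Differences present without the drug were tested in the DMSO libraries. CBFA2T3, a transcriptional corepressor gene, was at 51.9 ± 6.02 CPM (SD, n = 3) in WT cells and had 0 counts in insR cells, at least 369-fold lower. CALB2, a calcium-binding protein, was at 119 ± 6.11 CPM in insR and 0.655 ± 0.722 in WT cells, and the cadherin CDH11 at 72.8 ± 3.86 and 1.38 ± 0.289. MHC class II and most erythroid genes were higher in insR cells. edgeR called 3877 genes, 1866 higher and 2011 lower in insR cells, and 1373 differed at least 2-fold.

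CNTNAP4 had 0 counts in WT DMSO and was at least 73.6-fold higher in insR cells. With 1 count in WT DMSO, the ratio was 263 for MARCHF1 (95% counting interval 46.9 to 10400) and 247 for TRHDE (43.9 to 9780). SLC7A8, an amino acid transporter, was at 327 ± 23.7 CPM against 8.72 ± 0.296 in WT cells, and MAGEC1, MAGEC2, OTP and EMX2 were higher by log2 fold changes of 5.65, 5.16, 5.14 and 4.89. PARD3, PTPRCAP, NPW, RAPGEF5 and GJA4 had 0 counts in insR DMSO and were lower by at least 181, 108, 104, 81.3 and 77.1-fold. With 1 or 2 counts in insR DMSO, the ratio of WT to insR was 1080 for the ion channel PIEZO2 (194 to 42700), 473 for GAL (130 to 3910), 406 for DLK1 (112 to 3360) and 290 for IRX1 (51.6 to 11500).

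Of 22 erythroid genes 14 were higher and 3 lower in insR cells (camera adjusted p = 1.34e-12, 0.000699 with an estimated correlation), or 14 and 4 adjusted over the list alone, with EPB42 at 2.70. MHC class II genes were higher in 9 of 11 cases (adjusted p = 1.07e-08, 0.00209 with an estimated correlation), or 10 adjusted over the list alone, HLA-DRA at 1.67. Cholesterol synthesis genes were lower in 10 cases and higher in 1 (adjusted p = 0.0114, but adjusted p = 0.0657 with an estimated correlation), HMGCS1 at -1.22 and LSS at -1.44. Mast cell, basophil and eosinophil genes were higher in 6 cases and lower in 2 (adjusted p = 0.0464, but adjusted p = 0.206 with an estimated correlation and 0.0524 without insR DMSO replicate 1). Over all alternatives the adjusted p of the mast cell list ranged from 0.000245 to 0.206. The other 16 lists did not pass with camera, among them LSD1 complex genes (adjusted p = 0.109, and 0.000299 with fry), where 3 were higher and 5 lower, KDM1B at -1.55 and ZMYM2 at -1.09. ZMYM2 lies on chromosome 13, and KDM1B in a stretch of chromosome 6 whose genes were lower in insR cells. Without WT DMSO replicate 3, 7 lists passed in place of 4.

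Genes of chromosome 13 were lower in insR than in WT DMSO in 85% of 153 cases at a mean of at least 10 CPM, with a median log2 fold change of -0.73. The look by chromosome was not among the tests fixed beforehand, and chromosome 13 was named as the lowest of 23 chromosomes. The medians of the other 22 chromosomes lay between -0.0772 and 0.0816.

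**Figure D4:**
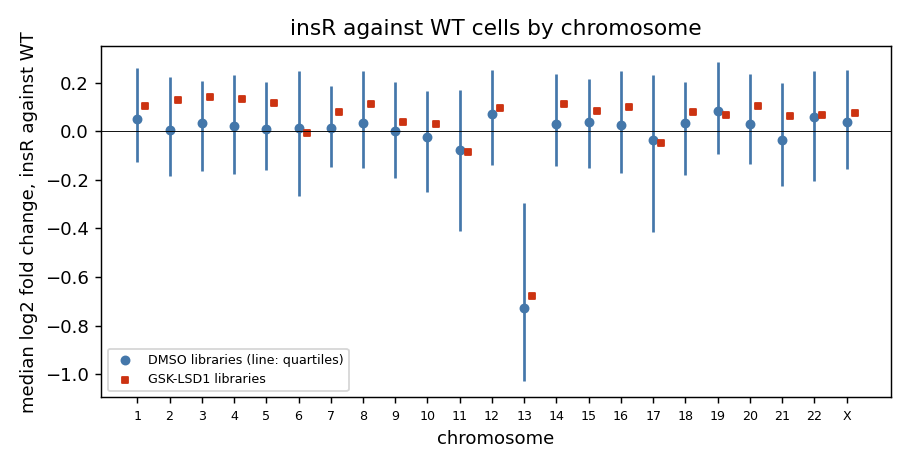
Median log2 fold change of insR against WT (y axis) for the genes of each chromosome (x axis) at a mean of at least 10 CPM, in DMSO libraries (circles, with quartile lines) and in GSK-LSD1 libraries (squares). Chromosome 13 lay at -0.73 and -0.68.

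The baseline difference of insR cells was set against the WT response across genes, which are not independent replicates. Pearson's r was -0.0357, against 0.489 to 0.544 in 50 simulations of unchanged groups that share the WT DMSO libraries. The covariance was -0.0302, against a simulated median of 0.029. The sign was shared by 48.3% of genes, against a simulated median of 66.9%. Of the genes raised by the drug in WT, 478 were higher and 623 lower in insR DMSO, where independent lists would share 423 and 456. Of those lowered by the drug, 544 were higher and 438 lower, against 421 and 453. The values for independent lists leave out the shared libraries, and the simulated ones leave out the effects. Real effects widen the spread of both comparisons, so the r that shared libraries alone would give here is smaller than in the simulations. The simulated r and sign share therefore do not give the values to expect here, and no conclusion is drawn from the gap in either. The sign of r turned, to 0.309 with no filter beyond 1 count and to 0.013, 0.0244 and 0.0082 without WT DMSO replicate 1, 2 or 3. Sharing the WT DMSO libraries alone gave a covariance of 0.0275 to 0.0324 in the simulations. That argues against the shared libraries as the source of the negative covariance in the main fit. Part of a positive relation may come from them. The shared libraries were not split because 1 side would hold 1 library.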

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

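The thinning to equal depth and the tests of mixed WT cells and of a fully responding share of insR cells were chosen only after the results were seen.

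The response to GSK-LSD1 differed between WT and insR cells in 3228 genes by the edgeR test of the interaction. Among genes raised in WT cells the adjusted p was 0.00103 for PI16, 0.014 for CLEC4A, 0.018 for MAPK13, 0.000117 for JAML, 0.00182 for SNX21, 1.1e-07 for TIMP2, 2.46e-05 for EPAS1, 6.05e-12 for PRR9 and 6.99e-05 for BACH2. The PI16 value was 1 without insR DMSO replicate 3, the CLEC4A value 0.0984 or 0.104 without its replicate 1 or 2, and the MAPK13 value 0.968 without its replicate 1. For PI16 and MAPK13 the library left out held the only reads of insR DMSO, so no fold could be estimated without it. Among genes lowered in WT cells it was 4.18e-12 for AQP1, 1.79e-16 for CD36, 1.94e-10 for OSBP2, 3.52e-08 for DHH, 3.9e-10 for HBA2, 5.85e-10 for HBG2, 1.26e-11 for HBA1, 5.8e-06 for CR2 and 9.89e-09 for EPB42. Among genes named for insR cells it was 0.000437 for DHRS9, 2.15e-09 for GDF3, 1.34e-07 for STAB1, 0.021 for FAM111B, 0.000311 for NSG1 and 0.00165 for SLC6A8. For gene lists the camera adjusted p was 1.02e-39 for erythroid genes, 5.25e-12 for cholesterol synthesis genes, 4.31e-09 for ribosome biogenesis genes, 4.63e-06 for cell cycle genes, 9.9e-07 for MHC class II genes, 0.000743 for monocyte and macrophage markers, 0.00104 for stem and progenitor genes and 0.00941 for heat shock and integrated stress genes. Of the 122 list members named for their low p under the drug, 75 differed in response. They were picked by the same drug comparisons that make up the difference, so a high share was built in. For scale, of the 2916 genes raised in WT cells 1465 had a more negative response in insR cells. Of the 2900 lowered in WT cells 1678 had a more positive one. The genes named for their largest drug changes were picked in the same way.

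GSK-LSD1 changed 5816 genes in WT and 65 in insR cells. The insR libraries were not lower in depth throughout. In DMSO, reads in genes ranged from 5789614 to 10141155 in insR and 5562853 to 7438754 in WT libraries. Under GSK-LSD1 they ranged from 4837096 to 6615832 in insR and 5022916 to 9599482 in WT libraries. With every library thinned to 4837096 reads, 5422 and 39 genes were called, a ratio of 139. The thinning shows only that the gap remained at equal depth. The insertion and any other difference between these cells stay open, as untested.

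The WT calls moved in insR cells by 7.9% of their WT median. WT cells mixed into the insR libraries would need a share of 8.32%, and 28 genes had upper limits of exact 95% counting intervals in insR DMSO below that share of their WT level, among them 0.518% for PIEZO2, 0.763% for GAL and 0.892% for DLK1, which argues against such a mixture. For a fully responding share of insR cells of that size, 18 genes induced in WT from near 0 rose in insR cells by a median of 0.265% of the WT increment (quartiles 0.13% and 0.636%), which argues against it, with RPP25 at 13.1% and SOX13 at 7.89%. For the WT calls as a set, a weaker response of the insR cells, larger at some genes than at others, may remain. Mixed shares below these limits stay open. Single genes went otherwise. DHRS9 went from 134 to 160 CPM up to 212 to 257 in WT cells, and from 47.3 to 51.1 up to 122 to 140 in insR cells, a larger fold. NSG1 rose in WT cells, from 12.5 to 14.5 CPM up to 15.7 to 20.3. In insR cells it fell, from 9.24 to 14.6 CPM down to 5.96 to 7.28, a call lost in several alternatives.

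For the WT response, the insR response and insR against WT in DMSO, the 10 splits of 6 libraries are too few for a share under 0.05. In each of these, 1 split, the real one, called as many genes (5816, 65 and 3877), and the highest other split called 0. For the difference in response, 11 of 100 relabellings of treatment within WT and within insR cells, the real one included, called at least its 3228 genes, up to 4188. These 11 kept the real grouping of the WT libraries and the other 89 called 0, so the count follows the WT response by construction and says nothing on chance in the difference.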

How the results depend on the processing

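Thinning to equal depth and the minimum mean CPM for the relation were chosen only after the results were seen. A change of at least 2-fold, which asks for more by construction, left 1557 genes in WT cells, 11 in insR cells, 993 for the difference in response and 1373 for insR against WT in DMSO, and an adjusted p under 0.01 left 25 in insR cells and 1896 for the difference. In insR cells 118 genes were called with no filter beyond 1 count, 39 by limma-trend and 39 at equal depth, and 28 to 45 with 1 library left out, where fewer samples enter. The WT, difference and DMSO counts stayed within 1.5 times under the other scalings, filters and tools, the replicate block and each library left out. The median insR movement of the WT calls was 0.176 for calls of at least 2-fold, 0.0595 at an adjusted p under 0.01 and 0.0467 to 0.0593 with 1 library left out. The r between the DMSO difference and the WT response was 0.309 with no filter beyond 1 count, -0.114 at a mean of at least 10 CPM and -0.0412 to 0.0244 with 1 library left out. The cause was not tested. Gene lists past the threshold in insR cells numbered 2 with an estimated correlation, 3 with fry and 3 to 5 with 1 library left out. They numbered 18 with fry in WT cells and 18 for the difference, and 2, 14 and 4 to 7 under these settings for insR against WT in DMSO. Fry asks another question than camera, and the cause of the other changes was not tested. With 1 library left out, uncalled results changed direction. The log2 fold change ranged over -0.144 to 0.0185 for ANPEP, -0.002 to 0.511 for CD79A and -0.032 to 0.916 for CD3D in insR cells, and -0.0533 to 0.931 for CD3D in DMSO. List means ranged over -0.223 to -0.0615 for mitochondrial mRNAs and -0.0906 to 0.119 for LSD1 complex genes in WT cells, -0.122 to 0.0882 for LSD1 complex genes in the difference, -0.116 to 0.0387 for inflammatory and -0.0259 to 0.0077 for ribosome biogenesis genes in insR cells, and -0.0379 to -0.0045 for ribosome biogenesis genes in DMSO. For these lists the direction is that of the camera test, which can differ from the sign of the mean. With the replicate number as a block 5818, 60, 3198 and 3897 genes were called, and STAT5 targets passed in DMSO (adjusted p = 0.0309, with 0.00195 to 0.27 over all alternatives). Same-numbered libraries had a median correlation of 0.0295, above 0.1 in 3 of 18 pairs, so the numbers were not taken to pair the libraries. Depth limits genes near 0.62 CPM, where a count of 0 does not show absence.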

Other observations

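The scan of gene windows along chromosomes and the look at the neighbours of KDM1A were chosen only after the results were seen. The look at whole chromosomes was not among the tests fixed beforehand.

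Stretches of neighbouring genes differed together between insR and WT cells in DMSO. In windows of 25 genes, with medians past a limit of 0.36 from shuffled gene order, those of chromosome 13 from SPATA13 to GPR180 had a median log2 fold change of -0.92, those of chromosome 6 from SLC22A23 to HLA-F -0.95, those of chromosome 11 from CTSC to DCPS -0.59 and those of chromosome 17 from SCARF1 to ELAC2 -0.88. On chromosome 17 a bounded run of 30 windows that began at ADORA2B was higher, at 0.74. Runs of 1 to 7 windows on chromosomes 10, 12, 14 and 16 also passed. In the GSK-LSD1 libraries, where the limit was 0.62, the windows of SPATA13 to VPS36 and SCARF1 to MYH10 were lower, at -0.88 and -0.86, and those of ADORA2B to LLGL1 higher, at 1.03. On chromosome 14 the windows of EIF5 to PPP1R13B were higher there, at 0.73, and those of TRMT61A to PPP1R13B in DMSO, at 0.37. The chromosome 11 stretch, of 113 windows in DMSO, passed in the GSK-LSD1 libraries only in separate runs of 1 to 8 windows, and the chromosome 6 stretch also broke into separate runs. The chromosome 13 stretch, of 101 windows in DMSO, passed there in runs of 78, 1 and 3 windows that ended at BORA, before GPR180. The limit of 0.62 in the GSK-LSD1 libraries was higher than the 0.36 in DMSO, and larger in size than the chromosome 11 median of -0.59. An unchanged stretch could thus break up, so the shorter runs do not show a change under the drug. When the drug response was scanned, WT cells had a run of 2 windows on chromosome 6, H2BC12 to ZNF184, at 0.56 (limit 0.50). No run passed for the insR drug response.

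The 24 tested neighbours of KDM1A on chromosome 1 had a median log2 fold change of 0.0727 in DMSO (quartiles -0.12 and 0.26), against -1.28 for KDM1A.

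Genes of chromosome 13 were lower in insR than in WT cells. Of these genes 85% were lower in DMSO. The median was -0.73 in DMSO and -0.678 in GSK-LSD1 libraries, and the drug moved it by -0.019 in WT and -0.0054 in insR cells. A candidate explanation, as a hypothesis, is fewer copies of chromosome 13 genes in the insR cells, which RNA alone does not show and a measurement of DNA copy number, not analysed here, would test. Whether such a difference came with the insertion or with how the cells were derived was not tested. Chromosome 13 was not alone, since the stretches of chromosomes 6, 11 and 17 given above also shifted, and their cause was not tested either.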
